A study of Homo sapiens with 16 samples.

How the data were processed

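RNA sequencing was analysed in 16 libraries of human myeloma cells. The libraries came from the lines MM.1s, RPMI8226 and KMS18 and from RPMI8226 made to overexpress the anti-apoptotic protein Mcl1. Each of these 4 backgrounds was given an empty pLKO.1 vector (called Vec here) or a short hairpin RNA (shRNA) against Gapdh, CD28 or CD86, with 1 library for each combination. RNA was isolated with Qiagen RNeasy columns and libraries were made with an Illumina TruSeq mRNA kit, per the labels' protocols. The hairpin sequences and the number of hairpins used against each target are not given in the sources used here.

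The authors deposited 1 table with FPKM values (fragments per kilobase of exon, scaled to the library total) for 23459 genes in each library, together with the exon length of each gene. In the same table the authors deposited log2 fold changes, with p-values and false discovery rates, for CD28 shRNA against Vec, CD86 shRNA against Vec and CD86 shRNA against CD28 shRNA. The submitters' processing notes list TopHat2 2.0.13, Picard, R 3.2.2 and edgeR 3.12.1 and the builds hg19, GRCh37 and mm9, without saying which step used which. The name of the deposited table marks Gapdh shRNA and the Mcl1 line as excluded, and the libraries that entered the authors' comparisons are not otherwise given in the sources used here. Of the gene entries 61 had no symbol and 4 shared a symbol with another entry, 5003 were at 0 in all libraries and 18456 had reads in at least 1.

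FPKM multiplied by exon length gave whole multiples of 1 step per library for 100% of values, within a tolerance of 0.02 of a read, so that reads per gene and library totals could be computed. Reads in genes ranged from 3914513 to 5900955 per library, and library totals from 4690942 to 7172402, with 80.8% to 84.4% of each total in genes. All 16 totals were even, and 74.8% to 77.9% of the low read numbers were even, so that the mates of a pair were probably counted separately and the number of independent fragments is lower than the reads given here. Reads were used for depth, thinning and 1 alternative test, and FPKM for all other tests. No strand setting is given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and reads of near-identical paralogs may be split between them.

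The knockdowns were compared in the 12 libraries of MM.1s, RPMI8226 and KMS18 with limma 3.58.1 (eBayes with a mean-variance trend) on log2(FPKM + 1), over 11316 genes with a mean of at least 1 FPKM. The model had a term for shRNA and a term for cell line, with 6 residual degrees of freedom. Each shRNA was given once to each line, so the lines were the replicates and paired the libraries. In all 18 pairs of libraries of the same line, deviations from the shRNA means were correlated (r 0.87 to 0.95 across genes), and the highest r between lines was -0.28. As each shRNA mean is taken over the 3 lines, r between lines is pushed negative, so the value between lines says nothing about the pairing. RPMI8226 overexpressing Mcl1 was compared with RPMI8226 in 8 libraries with a term for shRNA, over 11024 genes and with 3 residual degrees of freedom. The difference between its response to a shRNA and the mean response of the other lines was tested as an interaction over all 16 libraries and 11349 genes; with 1 library per shRNA in the Mcl1 line, the spread came from the other lines. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. All adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment, the threshold was 0.05, and tests were two-sided. Target genes were also tested by an exact sign-flip permutation over the 3 lines, which cannot give a p under 0.25. P-values measure only the spread between these libraries and lines. The 4 libraries of the Mcl1 line are a single derived line, not separate derivations.

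Gene lists were written down before the data were examined, as were the tests, the rule for naming genes and most alternative settings. Of 28 lists, those with at least 5 tested genes (22 in each comparison) were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with the correlation estimated from these libraries, and fry, were run as alternatives. With the estimated correlation camera called 0 lists in every comparison, also where the estimate was at or below the preset. Pro-apoptotic BCL2 relatives under CD28 shRNA had an estimate of 0.00998, and their camera p went from 0.00939 to 0.0408. A call lost this way therefore does not show by itself that the members vary together. The genes named are the target genes and MCL1, IRF4, ITGB1, ITGB7, MYC, PRDM1 and BCL2L11 whatever their result, up to 8 with the largest rise and 8 with the largest fall among those past the threshold with the same direction in every line or pair, and up to 4 per list past the threshold. Immunoglobulin, histone, HLA and sex chromosome marker genes were left out of that ranking. For Gapdh shRNA, for CD86 against CD28 shRNA and for the interactions of CD28 and CD86 shRNA they are GAPDH and the 5 with the smallest p in each direction. Any other gene named was chosen after its values were seen.

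Alternatives changed the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), the scaling (median of ratios), the trend, the line term, the libraries in the fit, the control and the replicates. After the data had been seen, limma's voom on reads, reads thinned to equal depth, leaving out genes with under 300 bp of exons, and leaving out genes with a hairpin heptamer were added. The list medians were also recomputed after rescaling and after thinning. Overlap between the responses to CD28 and CD86 shRNA was set against 50 simulations of unchanged groups that share the Vec libraries.

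A scan of 16148 heptamers, made after the changed genes had been seen, related the log2 change of each gene (limited to 1.5 either way) to the heptamers in its 3′ UTR, with terms for the length and GC content of the 3′ UTR. The 3′ UTRs came from GENCODE 29 and were matched by symbol for 10160 of 11316 tested genes (89.8%), each with at least 30 bp. Each shRNA was represented by the top heptamer and the one shifted from it by 1 base. Lower genes were compared with 10000 draws matched on 3′ UTR length in 20 bins. The scan was repeated on the Mcl1 line libraries alone.

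The tests were run on simulated data with known answers. For CD28 shRNA against Vec, over 11242 genes, the fit recovered 36.4%, 92.9% and 93.9% of genes changed by 0.5, 1 and 2 on the log2 scale, and 6.9% of calls were false. For the Mcl1 line, over 10907 genes, it recovered 69.1%, 99.4% and 99.7%, with 7.2% false. For the interaction, over 11296 genes, it recovered 1.5%, 29.0% and 85.7%, with 5.3% false. Camera called a list lowered by 0.5 in 20 of 20 draws over 11316 genes with independent errors, with 1 false list call in draws of 22 unchanged lists. The heptamer scan put a planted heptamer first in 20 of 20 draws over 10160 genes, and its lowest z over 20 shuffles was -4.97. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.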

Results

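Gene expression was measured by RNA sequencing in myeloma cells after knockdown of CD28, a co-stimulatory receptor, or of its ligand CD86, to study a survival signal of these cells. The 3 parental lines MM.1s, RPMI8226 and KMS18 and the RPMI8226 line overexpressing Mcl1 each received an empty vector (Vec) or a shRNA against Gapdh, CD28 or CD86, which makes 16 libraries. Between 3914513 and 5900955 reads per library fell in genes. The library with CD28 shRNA was the shallowest in every background, at 4000275 reads in MM.1s, 4577443 in RPMI8226, 4311353 in KMS18 and 3914513 in the Mcl1 line. The lines kept distinct profiles. FGFR3, a receptor tyrosine kinase, averaged 575 ± 101 FPKM (SD over 4 libraries of the line) in KMS18 against 0.231 in MM.1s and 0.437 in RPMI8226. The transcription factor MAF averaged 160 ± 21 FPKM in MM.1s and 230 ± 27 in RPMI8226 against 0.0764 in KMS18, and the integrin ITGB7 1360 ± 195, 690 ± 120 and 83.4 ± 31.7 FPKM in MM.1s, RPMI8226 and KMS18. CCND2, a cyclin, averaged 103, 62.5 and 24.3 FPKM in the same order. Markers of T cells, myeloid cells and stromal cells had medians of 0 to 0.152, 0 to 0.217 and 0 to 0.0345 FPKM per library.

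The targeted genes were examined first. CD28 fell under its shRNA to 71.7% ± 7.14 of the Vec level (SD, n = 3 lines), a log2 change of -0.47 (SE 0.10, limma adjusted p = 0.0295), and was at 67.5% in the Mcl1 line. CD86 under its own shRNA was at 54.9% ± 18.5 of Vec (log2 -0.62, SE 0.24, limma adjusted p = 0.315) and at 49.4% in the Mcl1 line. It was below Vec in all 3 lines without passing the test, at 1.10 to 5.28 FPKM and 18 to 106 reads per library. Over all libraries of the series CD86 had 1.10 to 12.3 FPKM and 18 to 186 reads. GAPDH, a glycolytic enzyme, was at 32.7% ± 21.2 under its shRNA (log2 -1.89, SE 0.37, limma adjusted p = 1). Its level ranged from 53% of Vec in MM.1s to 34.3% in RPMI8226 and 10.7% in KMS18, and was 21.3% in the Mcl1 line. CD86 was at 190% ± 81.6 of Vec under CD28 shRNA (log2 0.71, SE 0.24, limma adjusted p = 0.142; 211% in the Mcl1 line) and at 145% ± 54.7 under Gapdh shRNA. The exact sign-flip p was 0.25 for each target under its own shRNA, the smallest that 3 lines allow. Before adjustment over all genes, the limma p under the own shRNA was 0.000444 for CD28, 0.0271 for CD86 and 0.000368 for GAPDH. Without MM.1s, RPMI8226 or KMS18 the limma adjusted p of CD28 under its shRNA was 0.177, 0.101 and 0.179.

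**Figure D1:**
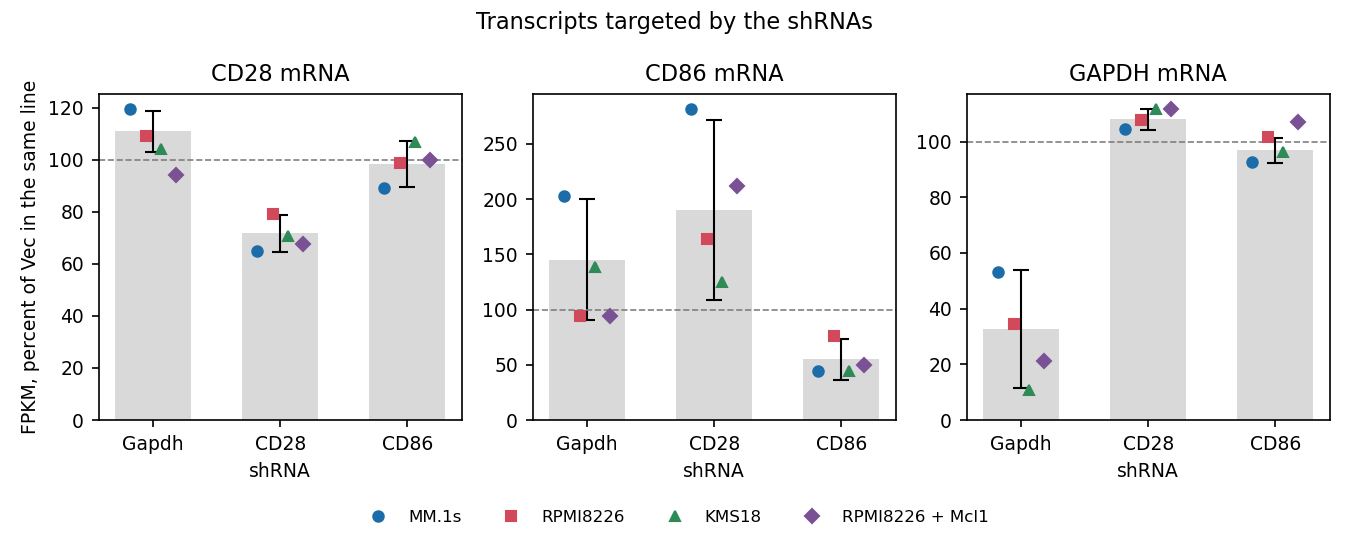
Level of CD28, CD86 and GAPDH as percent of the Vec library of the same line (y axis), by shRNA (x axis). Bars are means of MM.1s, RPMI8226 and KMS18, error bars SD, and points single lines including the Mcl1 line; CD28 averaged 71.7%, CD86 54.9% and GAPDH 32.7% under the shRNA against each.

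CD28 shRNA was compared with Vec to find the genes that follow CD28. Among the largest falls were SLC7A5, a transporter of large neutral amino acids (log2 -2.0, SE 0.17, adjusted p = 0.000449), C20orf27 (-1.75), the membrane transporter MFSD1 (-1.34) and SUCLA2, a subunit of a citric acid cycle enzyme (-1.33). MYC, a transcription factor of growth (-0.54, adjusted p = 0.0496), and BCL2L1, which encodes the survival protein BCL-xL (-0.54, adjusted p = 0.0363), also fell. The fall of MYC lay mainly in MM.1s (338 FPKM with Vec, 197 with CD28 shRNA) and KMS18 (353 and 210). It was small in RPMI8226 (401 and 377) and in the Mcl1 line (361 and 326). Among rises were the interferon-induced genes IFI6 (1.42) and IFIT3 (1.28), the dystroglycan gene DAG1 (1.06), PON2, a paraoxonase (1.06), and ITGB1, the beta-1 integrin (0.69, SE 0.12, adjusted p = 0.0143). Small RNA genes also passed on few reads. SNORD5 had 7 to 10 reads per parental library with Vec and 1 to 2 with CD28 shRNA, RMRP 2 to 4 and 4 to 12, and SNORD32A 1 to 2 and 3 to 7. SNORD74, SNORD18B and MIR138-1 had at most 3 reads with Vec and 0 with CD28 shRNA, and MIR4467 and SNORA80E at most 4 in any of these libraries. These numbers are too few to give the size of a change, and 0 to 4 reads are too few to settle a direction. MIR4467, SNORD32A, SNORD74 and MIR138-1 had values of the opposite sign in the Mcl1 line, as given with the flagged results. For IRF4, a transcription factor of plasma cells, the value was -0.50 (adjusted p = 0.0908), for PRDM1, another, -0.30 (0.412), for ITGB7 0.13 (0.744), for the pro-apoptotic BCL2L11 -0.03 (0.92), and for MCL1 0.14 (0.595).

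In all, 320 of 11316 genes passed, 81 higher and 239 lower, and all 320 had 1 direction in the 3 lines. The balance depended on the method: voom gave 235 higher and 324 lower. The authors' deposited table holds 401 higher and 405 lower at a false discovery rate under 0.05, and their calls, under 0.01, number 189 higher and 231 lower. In the Mcl1 line, outside this fit, 302 had the same direction and 16 the opposite one. The number fell to 38, 132 and 33 without MM.1s, RPMI8226 and KMS18, and of 36 named genes past the threshold only SLC7A5, C20orf27, MFSD1, SUCLA2 and IDI1 passed each time. Each of these named genes carries a CD28 shRNA heptamer in its 3′ UTR, as described with the 3′ UTRs. With the line term left out no gene passed and 204 had an unadjusted p under 0.05.

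**Figure D2:**
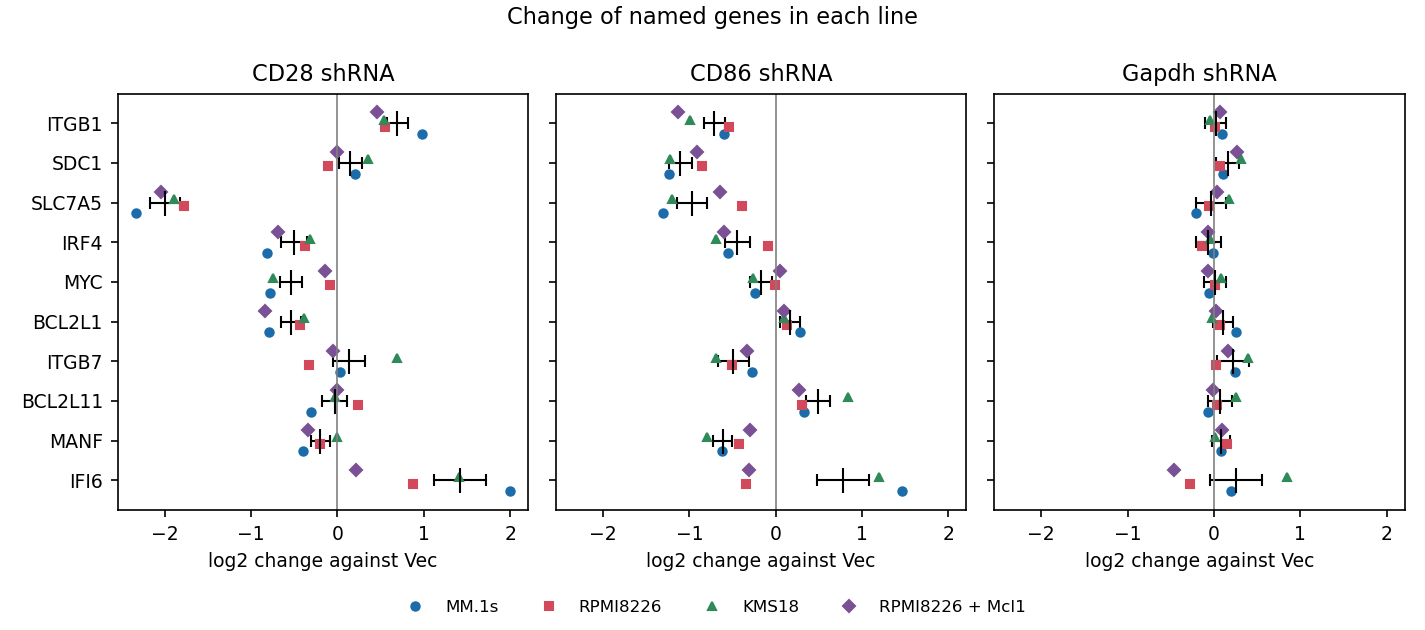
Log2 change against Vec (x axis) of ITGB1, SDC1, SLC7A5, IRF4, MYC, BCL2L1, ITGB7, BCL2L11, MANF and IFI6 (y axis) under each shRNA. Points are single lines including the Mcl1 line, black bars the limma estimate over 3 parental lines with its SE; genes were picked after their values were seen. ITGB1 lies to the right of 0 under CD28 shRNA (0.69) and to the left of 0 under CD86 shRNA (-0.71).

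Gene lists were tested for CD28 shRNA with camera, and none of its calls held with an estimated correlation. The control shRNA against Gapdh gave calls in the same direction for G1/S genes (median -0.19, against -0.21 under CD28 shRNA), MYC targets (-0.08 against -0.25) and heat shock genes (-0.11 in both). Of 30 tested MYC targets, mainly genes of ribosome production, 3 fell (14 adjusted over the list alone), among them FBL, a nucleolar methyltransferase (-0.49), SRM, spermidine synthase (-0.61), and LDHA, lactate dehydrogenase (-0.43), and all had estimates below 0 (camera adjusted p = 5.62e-09, and adjusted p = 0.417 with an estimated correlation). Of 24 genes of the G1/S transition and DNA replication 4 fell (11 adjusted over the list alone), all of the MCM helicase, MCM3 (-0.46), MCM2 (-0.40), MCM6 (-0.38) and MCM4 (-0.35) (camera adjusted p = 3.61e-07, and adjusted p = 0.417 with an estimated correlation). Of 23 interferon response genes 3 rose (9 adjusted over the list alone), IFI6, IFIT3 and BST2, a restriction factor (0.41), with a list median of 0.64 (camera adjusted p = 2.71e-07, and adjusted p = 0.417 with an estimated correlation). None of 25 NF-kB targets passed (4 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000461, and adjusted p = 0.417 with an estimated correlation). FAM46C (-0.58) and MYC fell among 20 plasma cell genes (4 lower and 1 higher adjusted over the list alone), and ITGB1 alone rose of 20 integrin and adhesion genes (2 adjusted over the list alone).

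For CD28 shRNA the calls of plasma cell genes, pro-apoptotic BCL2 relatives, p53 targets and heat shock genes (camera adjusted p = 0.0258 each) and of adhesion genes (0.0299) were also lost with an estimated correlation, where their adjusted p was 0.417 to 0.602. Single members past the threshold were BID, a pro-apoptotic BCL2 relative (0.53), and in the other lists KLF6 (0.52) and KLF10 (0.50), both transcription factors, P4HA2, a collagen prolyl hydroxylase (0.80), SREBF2, a regulator of cholesterol synthesis (0.44), IDI1, an enzyme of that pathway (-0.95), and DUSP2, a MAP kinase phosphatase (-0.68). None of 23 p53 targets or 18 heat shock genes passed over all genes (0 and 4 adjusted over the list alone). Of the pro-survival BCL2 family 4 genes were tested, too few for camera, and BCL2L1 passed. The remaining 13 lists, those of receptors and ligands of the CD28 family, FOXO targets, the unfolded protein response, ATF4 targets, cholesterol synthesis, glycolysis, hypoxia, G2/M, immediate early genes, MAF-related genes, FGFR3-related genes, B cell markers and ribosomal proteins, did not pass (camera adjusted p 0.135 to 0.813). Fry called 0 lists, camera called 5, 11 and 12 without MM.1s, RPMI8226 and KMS18, and the control shRNA against Gapdh gave 7 calls with camera, given with that comparison.

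CD86 shRNA was compared with Vec in the same way. The largest falls were CCDC167 (log2 -1.64, SE 0.14, adjusted p = 0.00183), GEMIN2, a protein of the SMN complex (-1.25), TGFBR2, a receptor for TGF-beta (-1.13), SDC1, the plasma cell surface proteoglycan CD138 (-1.11, adjusted p = 0.0106), SERINC1 (-1.05), SH2D3C (-0.98), SLC7A5 (-0.97) and SVIP (-0.96). ITGB1 fell as well (-0.71, SE 0.12, adjusted p = 0.0312). The rises were ZMAT3, a p53 target (0.82), ZNF823 (0.78), ATXN7L3B (0.59), the kinase gene DYRK2 (0.55), TCTA (0.53) and SH3BGRL (0.47). SNORD32A also passed as higher, on 1 to 2 reads per parental library with Vec and 5 to 9 with CD86 shRNA. IRF4 was at -0.44 (adjusted p = 0.236), ITGB7 at -0.49 (0.296), BCL2L11 at 0.49 (0.178), PRDM1 at -0.31 (0.515), MYC at -0.17 (0.6) and MCL1 at 0.27 (0.399), none past the threshold.

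In total 71 of 11316 genes passed for CD86 shRNA here, 7 higher and 64 lower, 71 with 1 direction in the 3 lines and 70 with the same direction in the Mcl1 line. With voom the balance was 51 higher and 161 lower. The authors' deposited table holds 73 higher and 232 lower at a false discovery rate under 0.05, and their calls, under 0.01, number 26 higher and 159 lower. Without MM.1s, RPMI8226 and KMS18 the number was 5, 9 and 0 (906 genes at an unadjusted p under 0.05 without KMS18), and none of the 19 named genes past the threshold passed each time.

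The most uniform group under CD86 shRNA was the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum. All 21 tested members had estimates below 0, with a median of -0.36. MANF, a secreted protein of that response (-0.61), passed over all genes, and 17 passed adjusted over the list alone, among them the chaperone HSPA5 (-0.40) and the disulphide isomerase PDIA4 (-0.51) (camera adjusted p = 6.7e-15, and adjusted p = 0.146 with an estimated correlation). The 17 members without the 3′ UTR heptamer of this shRNA, described with the 3′ UTRs, had medians of -0.42 in MM.1s, -0.23 in RPMI8226, -0.51 in KMS18 and -0.26 in the Mcl1 line. Of 24 genes of the ATF4 and amino acid response 23 were below 0, SLC7A5 passed and 10 passed adjusted over the list alone (median -0.46; camera adjusted p = 1.25e-11, and adjusted p = 0.413 with an estimated correlation). Of 20 plasma cell genes SDC1, MZB1, an endoplasmic reticulum protein of antibody-secreting cells (-0.47), and FKBP11, a prolyl isomerase (-0.53), fell, and 9 adjusted over the list alone (camera adjusted p = 1.28e-07, and adjusted p = 0.146 with an estimated correlation). Of 20 adhesion genes ITGB1 and SDC1 fell (3 adjusted over the list alone; camera adjusted p = 0.00154, and adjusted p = 0.416 with an estimated correlation).

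**Figure D3:**
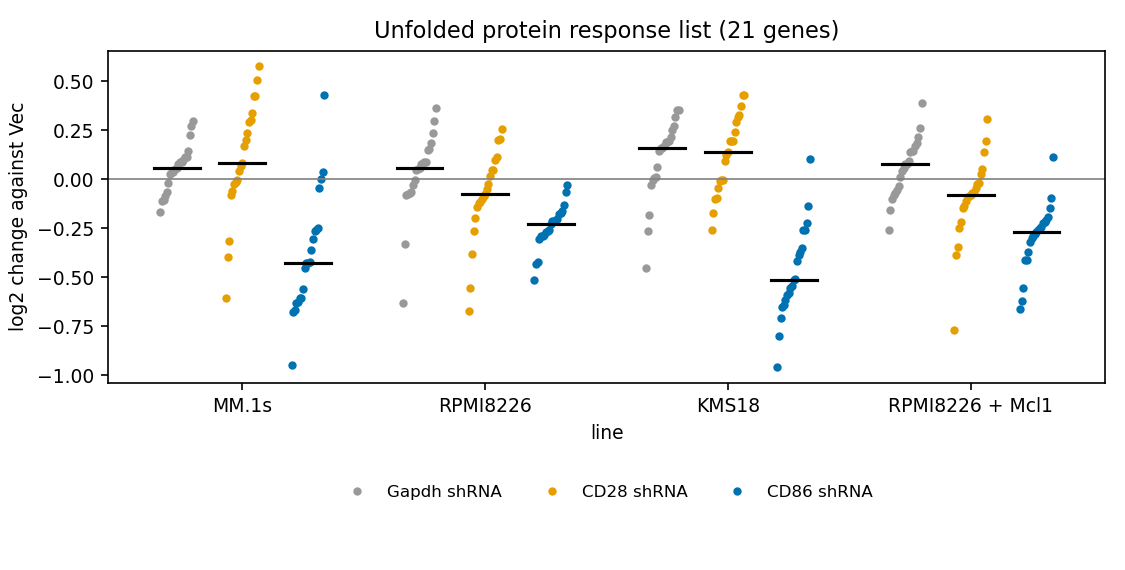
Log2 change against Vec (y axis) of 21 genes of the unfolded protein response, by background and shRNA (x axis). Points are genes and lines are medians; under CD86 shRNA the median over all parental lines was -0.36.

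Under CD86 shRNA camera also called heat shock genes (median -0.22, adjusted p = 0.000108), cholesterol synthesis (-0.17, 0.00017), ribosomal proteins (0.10, 0.000482), FOXO targets (0.18, 0.00399) and G1/S genes (-0.06, 0.0224), of which no member passed over all genes and 1 FOXO target was lower adjusted over the list alone. With an estimated correlation their adjusted p was 0.416 to 0.564. The control shRNA against Gapdh also gave lower calls for ATF4 targets (median -0.14, against -0.46 under CD86 shRNA) and heat shock genes (-0.11 against -0.22). It did so for G1/S genes too (-0.19 against -0.06), and its call of the unfolded protein response was in the opposite direction (0.08 against -0.36). Fry called 2 lists, plasma cell genes (adjusted p = 0.0249) and the unfolded protein response (0.0311). Without MM.1s, RPMI8226 and KMS18 camera called 5, 12 and 12 lists in place of 9. The other 13 lists, including interferon response, NF-kB targets, MYC targets, p53 targets and pro-apoptotic BCL2 relatives, did not pass (camera adjusted p 0.0704 to 0.991).

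Gapdh shRNA against Vec compared both controls. No gene passed in limma (smallest adjusted p 0.729, of SNORA68, which was at 0 FPKM with Gapdh shRNA in RPMI8226 and KMS18), against 402 at an unadjusted p under 0.05, and voom also called 0. Without MM.1s, RPMI8226 and KMS18 the count was 1, 2 and 0 (305 at an unadjusted p under 0.05 without KMS18). The smallest p among higher genes were of ANKIB1 (0.50), SNORD32A, PARM1 (0.39), ZNF749 (0.55) and SLX4IP (0.83), and among lower ones also of C1orf74 (-0.75), GAPDH, the nuclear import factor KPNA2 (-0.55) and CMC2 (-0.47). Camera still called 7 lists, and 2, 8 and 8 without MM.1s, RPMI8226 and KMS18. The other 15 did not pass (camera adjusted p 0.051 to 0.96). All 24 G1/S genes had estimates below 0 (median -0.19, camera adjusted p = 2.8e-11, and adjusted p = 0.695 with an estimated correlation). MYC targets (-0.08, 0.00213), heat shock (-0.11, 0.00457), ATF4 targets (-0.14), glycolysis (-0.07) and the unfolded protein response (0.08, each 0.0197) and G2/M (-0.08, 0.028) were called too, with adjusted p of 0.721 to 0.941 for all but glycolysis (0.695) with an estimated correlation. GAPDH was the glycolysis member that passed adjusted over the list alone.

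The receptor and the ligand knockdowns were compared directly. Between CD86 and CD28 shRNA 1076 of 11316 genes differed, 612 higher and 464 lower with CD86 shRNA, and rescaling by the median of ratios gave 46.5% higher in place of 56.9%. Higher with CD86 shRNA were MFSD1 (1.48), HAUS1, a spindle protein (1.20), C20orf27 (1.71), the small GTPase gene ARF3 (1.09) and PAIP2, a translation regulator (1.14). Lower were ITGB1 (-1.40, SE 0.12, adjusted p = 0.000307), CCDC167 (-1.55), SH2D3C (-1.57), SDC1 (-1.25) and UBAC1 (-0.78), and GAPDH was at -0.16 (adjusted p = 0.824). The target genes differed as well, CD28 by 0.45 and CD86 by -1.33. Of 21 genes of the unfolded protein response 13 were lower with CD86 shRNA (16 adjusted over the list alone), among them CALR (-0.56), HYOU1 (-0.73) and HSPA5 (-0.48) (camera adjusted p = 2.93e-10, and adjusted p = 0.568 with an estimated correlation). Of 23 interferon genes 5 were lower (8 adjusted over the list alone; camera adjusted p = 9.98e-06, and adjusted p = 0.579 with an estimated correlation). Camera also called adhesion genes, NF-kB targets, ATF4 targets and cholesterol synthesis as lower and G1/S genes, MYC targets and ribosomal proteins as higher (camera adjusted p 6.47e-05 to 0.00392). All 9 calls were lost with an estimated correlation (adjusted p 0.568 to 0.664), fry called 2 of them, the unfolded protein response (adjusted p = 0.0381) and adhesion genes (0.0427), and the other 13 lists did not pass (camera adjusted p 0.0733 to 0.855). Without MM.1s, RPMI8226 or KMS18 the count was 171, 525 and 137, and with only the libraries of both shRNAs it was 10; the 10 named genes other than GAPDH passed without each line. Of these 10, MFSD1, HAUS1, C20orf27, ARF3 and PAIP2 carry a CD28 shRNA heptamer in the 3′ UTR, and ITGB1, CCDC167, SH2D3C, SDC1 and UBAC1 a CD86 shRNA heptamer, as described with the 3′ UTRs.

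Few genes passed in both knockdowns. The shared lower genes were ASF1B, ME2, SLC7A5 and TMEM214, 4 against 1.35 for independent lists, and the shared higher gene was SNORD32A, 1 against 0.0501. The 3′ UTR of SLC7A5 carries heptamers of both the CD28 and the CD86 shRNA, as described with the 3′ UTRs. SNORD32A had 1 to 2 reads per parental Vec library and was also above Vec in all 3 lines under the control shRNA against Gapdh. ITGB1 was higher with CD28 and lower with CD86 shRNA, 1 gene against 0.458. Without MM.1s, RPMI8226 or KMS18, 0, 2 and 0 genes passed in both with the same direction. Because both comparisons share the Vec libraries, their log2 changes correlate by chance. The observed r across genes was 0.25 and that of 50 simulations of unchanged groups 0.50, with a covariance of 0.0166 against 0.0136 and 0.04 shared calls on average. With Vec as the control of 1 shRNA and Gapdh as that of the other, r was -0.05 and 0.07.

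The authors' deposited table held calls for the same comparisons. The authors called 420 genes for CD28 shRNA (189 higher, 231 lower), 185 for CD86 shRNA and 879 for CD86 against CD28 shRNA, all with a false discovery rate under 0.01. At a rate under 0.05, the limit used here, the table holds 806, 305 and 1545 genes. Of these, 293, 70 and 921 also passed here, all with the same sign, and log2 changes correlated across 11312 genes at r 0.944, 0.943 and 0.945. In the authors' deposited table IRF4 had a log2 change of -0.50 (rate 0.009) under CD28 shRNA and of -0.47 (0.0308) under CD86 shRNA, and CD86 had 0.90 (0.0288) under CD28 shRNA and -0.85 (0.116) under its own.

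Lower genes shared short sequences in their 3′ UTRs, in a scan made after the calls were known. For CD28 shRNA the heptamer CTGTGTT ranked first of 16148 (z -18.1) and TGTGTTA second (-13.3), and 1 or both were in 151 of 220 lower genes with a 3′ UTR (68.6%, against 31.0% of the rest). For CD86 shRNA TCAAGCA (z -18.7) and TTCAAGC (-18.1) led, and were in 47 of 64 lower genes (73.4% against 20.4%). As the heptamers were chosen on these libraries, the shares alone are not a separate test. A scan of the Mcl1 line libraries alone ranked the same heptamers first and second, with z of -15.1 and -11.0 for CD28 shRNA and -16.0 and -15.6 for CD86 shRNA. SLC7A5, C20orf27, MFSD1, SUCLA2, IDI1, BCL2L1, DUSP2, LDHA, MCM3, MCM6, HAUS1, ARF3, PAIP2 and CD28 itself carry a CD28 shRNA heptamer. So do genes that did not pass under CD28 shRNA, such as IRF4, PRDM1, BCL2L11, MCL1 (0.14), and SDC1, TGFBR2, SERINC1 and SVIP, which are among the largest falls under CD86 shRNA. The 3′ UTR of CD86 carries no CD86 shRNA heptamer; of both, TTCAAGC occurs elsewhere in the CD86 transcript and TCAAGCA does not. CCDC167, GEMIN2, TGFBR2, SDC1, SERINC1, SH2D3C, SLC7A5, SVIP, UBAC1 and ITGB1 carry a CD86 shRNA heptamer. So do IRF4 and CD28, which did not pass under CD86 shRNA. MYC, FBL, SRM, MCM2, MCM4 and ITGB7 carry no CD28 shRNA heptamer, and MANF, MZB1, FKBP11 and ITGB7 no CD86 shRNA heptamer. Of higher genes 12 of 71 (16.9%) with CD28 shRNA and 0 of 6 with CD86 shRNA had the heptamers of that shRNA. With all genes that carry them left out of the test, 59 genes passed for CD28 shRNA and 0 for CD86 shRNA (limma, 1065 at an unadjusted p under 0.05). Each gene is fitted on its own, so this changes the adjustment and not the log2 change of a gene. The 17 lower genes without a CD86 shRNA heptamer had a median of -0.56 (median SE 0.0891 with all genes tested and 0.0888 with those left out), and their smallest adjusted p became 0.0734, as the adjustment no longer held the genes with the smallest p.

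**Figure D4:**
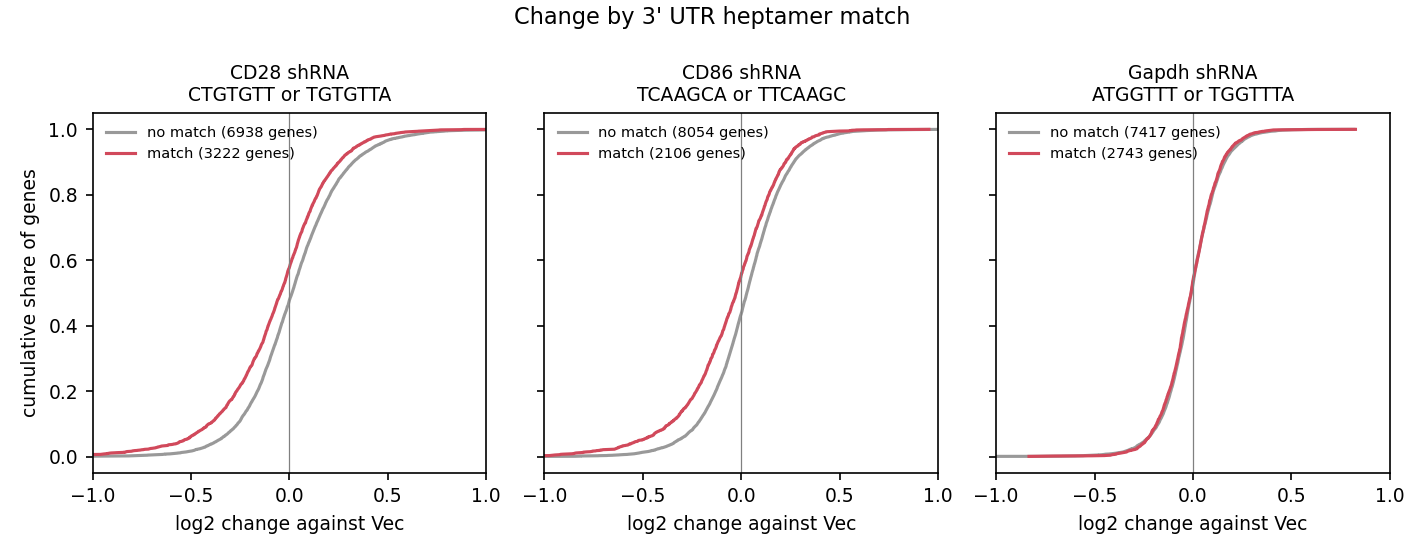
Cumulative share of genes (y axis) by log2 change against Vec (x axis) for genes with and without the heptamers of each shRNA in the 3′ UTR. Genes with the heptamers numbered 3222 for CD28, 2106 for CD86 and 2743 for Gapdh shRNA of 10160; the curve of genes with the heptamers lies to the left.

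The Mcl1 line was compared with RPMI8226 over the 4 shRNAs. MCL1 itself was higher by 1.43 (SE 0.09, adjusted p = 4e-05), 2.47-fold with Vec, 2.41-fold with Gapdh shRNA, 2.67-fold with CD28 shRNA and 3.49-fold with CD86 shRNA. The largest rises were CD177, a neutrophil surface protein (4.53), KEL, the Kell blood group protein (4.08), SFRP2, a modulator of Wnt signals (3.91), the small heat shock protein gene HSPB8 (3.57), MYO1E, a myosin (3.15), G0S2 (2.93), PAGE5 (2.89) and LBH (2.84). The largest falls were APCDD1, a Wnt inhibitor (-4.50), TSPAN7 (-4.12), CFC1B (-3.39), the complement receptor CR2 (-3.37), MS4A1, which encodes CD20 (-3.33), KRTAP3-2 (-3.13), CFC1 (-3.08) and ETS1, a transcription factor (-3.04). CFC1 and CFC1B are near-identical, and their reads may be split between them. CD28 (-0.52), ITGB7 (-0.20), MYC (-0.17) and GAPDH (-0.39) were lower, ITGB1 (0.55) and BCL2L11 (0.20) higher, and CD86 (-0.26, adjusted p = 0.164), IRF4 (0.20, 0.153) and PRDM1 (0.04, 0.768) did not pass. Of 104 named genes that passed, 98 passed without each pair in turn. GAPDH did not pass without the Vec pair (adjusted p = 0.0707) or the CD28 shRNA pair (0.0515), and BCL2L11 did not without the Vec, Gapdh shRNA or CD86 shRNA pair (0.117, 0.106 and 0.108). The estimate for GAPDH includes the pair in which it is the target, at 209.5 FPKM in the Mcl1 line against 402.3 in RPMI8226. The other pairs were at 985.3 against 1172 with Vec, 1100 against 1265 with CD28 shRNA and 1054 against 1192 with CD86 shRNA.

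Of 11024 genes 3793 differed between the Mcl1 line and RPMI8226, 2146 higher and 1647 lower, 3732 of them with 1 direction in all 4 pairs, and 224 rose and 215 fell by at least 1 on the log2 scale. Without the term for shRNA 2459 passed. Median-of-ratios rescaling gave 49.7% higher in place of 56.6%.

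Gene groups differed between the lines. ATF4 targets were higher, 15 of 23 with none lower, including PHGDH (2.81) and PSAT1 (1.51) of serine synthesis, as were 14 of 18 heat shock genes, including HSPB1 (0.74) and HSPA8 (0.71) (camera adjusted p = 2.35e-05 each, and adjusted p = 0.48 and 0.239 with an estimated correlation). NF-kB targets were higher in 15 and lower in 1 of 24, including NFKB2 (1.05), NFKBIA (0.86) and BIRC3 (1.39) (camera adjusted p = 0.000266), and G1/S genes in 15 and 1 of 24, including RRM2 (0.82) (0.000204); with an estimated correlation their adjusted p was 0.239 and 0.411. Interferon genes were lower in 13 and higher in 2 of 24, IFI6 (-1.55) and OAS2 (-1.29) lower and CXCL10, a chemokine (1.74), higher (0.000266, and adjusted p = 0.523 with an estimated correlation). The unfolded protein response was lower in 12 and higher in 2 of 21, including HERPUD1 (-0.45) and HSPA5 (-0.26) (0.000256), and plasma cell genes were lower in 11 and higher in 3 of 19, including MZB1 (-0.81), MEF2C (-2.19) and DERL3 (-1.57) (0.00552), both with an adjusted p = 0.239 with an estimated correlation. Camera also called G2/M (13 higher, 4 lower, 0.00943), ribosomal proteins (1 higher, 6 lower, 0.00359), MYC targets (13 higher, 1 lower, 0.0165) and cholesterol synthesis (1 higher, 8 lower, 0.0483). With an estimated correlation none of the 11 calls held, with adjusted p of 0.239 to 0.615. For NF-kB targets the estimate was -0.0244, below the preset 0.01, and the camera p went from 7.26e-05 to 0.0217. The loss of these calls thus does not show by itself that members vary together. Fry, which tests whether the genes of a list move 1 way and does not compare them with other genes, called 8 of the 11 and 7 lists that camera did not call. Cholesterol synthesis, interferon genes and ribosomal proteins were not called by fry (adjusted p 0.0623 to 0.212).

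Other genes that differed in the Mcl1 line were CXCR4, a chemokine receptor (1.42), the ligand gene CD276 (2.58), the cadherin gene CDH2 (-2.62), DEPTOR, an mTOR inhibitor (-2.40), DUSP5 (-2.18), and the pro-apoptotic PMAIP1 (0.89). Of 6 tested B cell markers 3 were higher, with HLA-DRA (3.81) and CIITA (1.10), and 3 lower, with CR2 and MS4A1. CD68 (0.86) and ITGAM (1.57) of the myeloid markers, FN1 (0.80) and VIM (1.16) of the stromal markers and CD7 (0.57) of the T cell markers were also higher. CD7 did not pass without the Vec pair (adjusted p = 0.0509) or the Gapdh shRNA pair (0.0504), and ITGAM had too low a mean to be tested without the CD28 shRNA pair. The 11 lists not called, from receptors of the CD28 family to hypoxia and glycolysis, had camera adjusted p of 0.0538 to 0.915. Median, mean and test differed in sign for some lists that were not called, such as FGFR3-related genes (median 0.15, mean -0.36), and for no called list.

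Whether the Mcl1 line responded differently from the other lines was tested for each shRNA. The Mcl1 line has 1 library per shRNA, so the spread in this test comes from the parental lines and that library is assumed to vary like theirs. For CD28 shRNA 1 of 11349 genes passed, CCK, which encodes the hormone cholecystokinin (-2.27), with 371 genes at an unadjusted p under 0.05 and 0 by voom. CCK had 0 to 6 reads in every parental library, so it could not fall there, and its p says nothing about a difference between the lines. For CD86 shRNA 0 passed in limma (smallest adjusted p 0.484) with 293 at an unadjusted p under 0.05 and 0 by voom. For Gapdh shRNA 0 passed with 213 at an unadjusted p under 0.05. The other genes with the smallest p did not pass. For CD28 shRNA they were TNNI2, SNORD74, MIR4674, COMMD3 (0.94) and MOB3C (1.06) among higher differences and SNORD32A, SNORD44, SNORD33 and C2orf27A among lower ones (adjusted p 0.137 to 1). For CD86 shRNA they were MT1G, ZNF724P, TNNI2, HIATL2 (1.58) and FAM127B (1.29), and SNORA31, SNORD38B, MED18 (-1.14), SNORD38A and ST20-AS1 (adjusted p 0.484 to 1). GAPDH differed by 0.05 and 0.14 (adjusted p = 1 each). The call of CCK was lost without each parental line in turn, with 0, 0 and 2 genes passing without MM.1s, RPMI8226 and KMS18.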

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

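The tests below on 3′ UTR length, on genes without a heptamer, on the unfolded protein response and on the Mcl1 line were chosen only after the results were seen, and the splits of the libraries and the comparison of 3′ UTR with coding sequence were fixed before.

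Genes whose response in the Mcl1 line stood apart from that of the parental lines were picked out by the test of that difference or by opposite directions. CCK differed by -2.27 under CD28 shRNA, with -2.19 in the Mcl1 line and 0.08 in the parental lines. It had 162, 137, 18 and 108 reads with Vec, Gapdh, CD28 and CD86 shRNA in the Mcl1 line and 0 to 6 elsewhere. The parental lines barely express the gene and the Mcl1 line has 1 library per shRNA, so this shows 1 low library and no tested difference in response. Some small RNA genes had the opposite direction in the Mcl1 line. The log2 values of FPKM + 1 there were -1.81 for MIR4467, -3.12 for SNORD32A, 2.79 for SNORD74 and 0.28 for MIR138-1 under CD28 shRNA, and -0.16 for SNORD32A under CD86 shRNA. These oppositions were not tested as such. With 0 to 9 reads per library the values depend on the added 1 and give neither the size of a change nor a firm direction. In the Mcl1 line MIR138-1 had 1 read with Vec and 1 with CD28 shRNA, and SNORD32A had 4 with Vec and 3 with CD86 shRNA.

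The first pattern is that genes lower under each hairpin share a 3′ UTR heptamer. Long 3′ UTRs are argued against: a scan of the Mcl1 line libraries alone, with 3′ UTR length as a term, put the same heptamers first and second, and with heptamers that can so be chosen outside the parental libraries, 151 lower genes carry the CD28 heptamers where length-matched draws gave at most 91, and 47 carry the CD86 heptamers where draws gave at most 25. Pairing of the hairpin with its seed may account for these genes. The heptamers went with larger falls in 3′ UTRs than in coding sequence, by -7.8 SE for CD28 and by -7.8 SE for CD86 shRNA. In the Mcl1 line the differences were -5.2 and -7.6 SE. The control shRNA against Gapdh is also a hairpin, and its heptamers gave -3.5 SE and only -1.3 SE in the Mcl1 line. These were ATGGTTT and TGGTTTA, first and second in the scan (z -7.4 and -6.2) and again in the Mcl1 line (-7.8 and -6.0). Loss of the target stays open for the 69 and 17 lower genes without a heptamer and for those with one, as no second hairpin was analysed here. From 3′ UTR length 66.7 and 10.8 of the lower genes would be expected to carry a heptamer, so carrying one does not tell why a gene fell. The heptamers were chosen on 3′ UTRs in the parental libraries, which favours the differences in SE given above. The octamer formed by the CD28 heptamers, CTGTGTTA, is in the CD28 transcript, and that of the Gapdh heptamers, ATGGTTTA, in the GAPDH transcript. Of the CD86 heptamers TTCAAGC is in the CD86 transcript and TCAAGCA is not. The presence of a heptamer in the target transcript does not decide the question. Pairing is therefore a hypothesis that the hairpin sequences would settle.

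The second pattern is the lower unfolded protein response under CD86 shRNA. Pairing with these heptamers in the 3′ UTRs of the members themselves is argued against. The members without a 3′ UTR heptamer had a highest median over the 4 backgrounds of -0.23 against 0.06 to 0.16 under Gapdh shRNA. Pairing elsewhere in the members was not examined. Over all genes scanned, the CD86 heptamers in coding sequence had an effect of -0.07 (SE 0.005) in the parental lines. Members that vary together between cultures remain possible, as the correlation estimated for the list was 0.283 and camera called 7 lists for the control hairpin. The camera adjusted p with that correlation was 0.146. No list of any comparison was called that way, so the lost call does not decide the question. Loss of CD86, in which 17 members passed adjusted over the list alone, and an indirect effect of other genes that the hairpin lowers cannot be told apart from these libraries, since 1 knockdown per line was analysed.

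The third pattern is the many genes that differ between the Mcl1 line and RPMI8226. Libraries of another line are argued against, as 98.7% of 76 genes that only RPMI8226 expresses among the parental lines were above 1 FPKM in all 4 libraries, against 11.1% of MM.1s and 5.56% of KMS18 genes. Depth is argued against by 3556 calls after thinning to equal depth. Mcl1 itself, at least 2.41-fold higher in each pair, and drift or selection of a single derived line may each account for the differences, and no second such line was analysed here.

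Other splits of the same libraries were counted. For CD28 shRNA, CD86 shRNA, Gapdh shRNA and CD86 against CD28 shRNA the 10 splits are too few for a share under 0.05; 1, 1, 10 and 1 of them gave as many genes as the real split, whose counts were 320, 71, 0 and 1076, with 0, 1, 0 and 0 for the highest other. Among splits that part all 3 pairs, 4 in number, the highest others were the same. For the Mcl1 line 1 of 35 splits, the real one, gave as many as 3793, the highest other gave 0, and 3 could not be fitted. The shRNAs pair these libraries, and the splits that part all 4 pairs, 8 in number, are too few for a share under 0.05; the highest other among them gave 0.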

How the results depend on the processing

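Voom, thinning, leaving out short genes and leaving out genes with a hairpin heptamer were chosen only after the data were seen; the other alternatives were planned. Of the values of single genes under an alternative 2597 kept direction and side of the threshold, 444 lost it, 15 gained it and 8 reversed; of counts and target genes 105 held, 62 moved and 7 lost the threshold. The cause of the changes below was not tested unless given.

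The counts of changed genes (main values 320 for CD28 shRNA, 71 for CD86 shRNA, 0 for Gapdh shRNA, 1076 for CD86 against CD28 shRNA) moved by over 1.5 times as follows. With no filter they were 147 and 30 for CD28 and CD86 shRNA and 605 for CD86 against CD28 shRNA, and the interactions gave 113 and 115; a mean of at least 5 FPKM gave 109 for CD86 shRNA and 0 for the CD28 interaction. Limma without the trend gave 196 and 35. With no replicate block, that is without the pairing by line, 0, 0 and 0 genes passed for CD28, CD86 and CD86 against CD28 shRNA (204, 83 and 350 at an unadjusted p under 0.05). The line differences then enter the spread. For the Mcl1 line 2459 passed without its pairing by shRNA, where the shRNA differences enter the spread. Leaving out 1 line at a time gave 33 to 132, 0 to 9, 0 to 2 and 137 to 525, 0 to 2 for the CD28 interaction and 0 to 2 for genes shared by both knockdowns. Leaving out a pair of the Mcl1 comparison gave 2750 to 3207, within 1.5 times 3793. With only both shRNAs compared, 89, 7 and 10 passed; with the Mcl1 line added to the other lines, 1036, 282 and 2122; without the Gapdh libraries, 156 and 15. Gapdh as the control gave 128 for CD86 shRNA, and the mean of both controls 583 and 205. Leaving out genes with a heptamer left 59 and 0 (1065 at an unadjusted p under 0.05). Fewer genes were then tested, which changes the adjustment and slightly the SE, but not the log2 changes. Voom gave 559 and 212 (42.0% and 24.1% higher in place of 25.3% and 9.86%), 0 for the CD28 interaction and 19 shared genes. Log2(FPKM + 0.1) gave 6 and 4 for the interactions and 2 shared genes, and Gapdh as the control of CD28 shRNA with Vec for CD86 shRNA 3.

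The change of CD28 under its shRNA was -0.47 and no longer passed with no filter (adjusted p = 0.0587), without the trend (0.0644), with no replicate block (1) or with only both shRNAs (0.0824), and was -0.41 to -0.55 without each line (0.101 to 0.179). Gene lists called with an estimated correlation were 0, 0, 0 and 0 for CD28, CD86 and Gapdh shRNA and the Mcl1 line, in place of 9, 9, 7 and 11, and fry called 0, 2 and 0; without each line 5 to 12, 5 to 12 and 2 to 8 were called, and 3 for Gapdh shRNA without heptamer genes. Signs turned for BCL2L11 under CD28 shRNA (-0.17 to 0.10 without each line, above 0 without MM.1s), ITGB7 under CD28 shRNA (-0.15 to 0.36, below 0 without KMS18, and -0.09 with the Gapdh control), CD28 under CD86 shRNA (0.04 without MM.1s) and PRDM1 in the Mcl1 line (-0.07 to 0.09 without each pair, below 0 without the Vec pair, and 0.00 after thinning). GAPDH under CD86 shRNA turned to 1.84 with the Gapdh control and 0.90 with the mean control, because that control is itself a GAPDH knockdown. No called list changed the sign of its median after rescaling or thinning. TMM and count-based tools were not run on the FPKM values. CD86 under its own shRNA passed in no alternative (adjusted p 0.0867 to 1; 0.371 after thinning and 0.354 with voom), and whether depth is the cause was not tested. The small RNA genes past the threshold under CD28 or CD86 shRNA that are named rest on at most 12 reads per parental library with Vec or that shRNA.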

Other observations

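The scans of heptamers and of genes by heptamer were chosen only after the changed genes were seen.

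Besides the heptamers of lower genes, GCACTTT was associated with slightly higher expression under CD28 shRNA (effect 0.04, z 6.0 of 16148 tested, and z 2.8, rank 36, in the Mcl1 line). No cause was tested. Genes with 2 or more CD28 or CD86 heptamers were lower than those with 1 by -0.086 and -0.089, and the reverse complements had effects of -0.002 and -0.001. The heptamers of the other hairpin showed no excess among lower genes, at 18.6% against 20.8% for CD86 heptamers under CD28 shRNA and 26.6% against 31.7% for CD28 heptamers under CD86 shRNA.

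Under CD86 shRNA the plasma cell genes without the CD86 heptamer, 16 of those tested, had medians of -0.24, -0.21, -0.16 and -0.32 in MM.1s, RPMI8226, KMS18 and the Mcl1 line, and the 16 ATF4 targets without it -0.27, -0.20, -0.78 and -0.50. Under CD28 shRNA the same plasma cell genes had medians of -0.22, -0.1, 0.03 and -0.16, and the same ATF4 targets -0.39, -0.12, 0.03 and -0.45. Among the T cell markers CD3E was lower with CD86 than with CD28 shRNA (-1.24, adjusted p = 0.0292). The pro-survival genes BCL2L1 (0.71, adjusted p = 0.00553) and BCL2 (-0.53, 0.0143) differed between the same shRNAs in opposite directions. These genes were named after their values were seen.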
